A study of Homo sapiens with 8 samples.

How the data were processed

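Total RNA from 4 human prostate cancer cell lines (C4-2B, DU145, PC3 and VCaP) was labelled from 400 ng with a whole-transcript kit and hybridised to Affymetrix arrays, per the labels' protocols. Each line had been treated for 48 hours with a small interfering RNA (siRNA) against DNA-PK or with a non-targeting siRNA. There were 8 arrays, 1 for each treatment in each line. The labels name the line and the siRNA of every array, and groups were taken from those labels.

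The deposited values are log2 signals per probe set. The submitters' processing notes name oligo and RMA (robust multi-array average, which corrects the background, makes the distributions of all arrays alike and summarises the probes of a set), with no version. Making distributions alike removes any change shared by most genes, so a difference reported here is relative to the bulk of the transcripts on an array. Over all probe sets, the medians of the arrays lay between 2.94 and 2.99 on the log2 scale. Array scanner files were not used here, so no detection call or scan batch could be examined. The number of arrays limits the precision.

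The table held 53617 probe sets. The platform annotation listed 25713 of them with a gene. Of those, 23871 had exactly 1 gene symbol and 1842 had several, and 27904 probe sets were unnamed here. Symbols were updated through the Entrez identifier for 22569 probe sets, with the RefSeq gene table of assembly GRCh38.p14. The genome build of the array design is not given in the sources used here, so no coordinates are printed. Only probe sets with 1 symbol were used, and the probe set with the highest mean over all 8 arrays stood for each of the 22395 genes (632 symbols had over 1 probe set). Genes with a mean at or below the 25th percentile (2.51 on the log2 scale) were set aside, which left 16796. KLK3, TMPRSS2, ERG and VIM served as identity markers.

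Differences are DNAPK siRNA minus non-targeting siRNA on the log2 scale. The main comparison was a limma fit (lmFit and eBayes, version 3.58.1 under R 4.3.3) with the cell line as a block, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. It had 3 residual degrees of freedom, and 7.55 in total with the prior. The cell line pairs the arrays by design. After subtracting the group means, the correlation across genes was 0.864 to 0.918 for the arrays of a line and at most 0.0135 for arrays of different lines. The subtraction itself lowers the correlation between lines. Without it, the correlation was 0.974 to 0.990 within a line and at most 0.892 between lines. The cultures of a line were not replicated, so p-values measure the spread of the response between 4 lines. A sign-flip test of 4 pairs cannot give an exact 2-sided p below 0.125.

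Before the data were examined, 30 gene lists were fixed. They covered the Wnt pathway (ligands and receptors, beta-catenin components, non-canonical components, antagonists and target genes), DNA repair, the cell cycle, stress, immune, metabolic and lineage genes, and markers of other cell types. PRKDC was left out of every list. Some of what was planned or tested is not reported here. A list with at least 8 measured members was tested with camera (limma) at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation, fry and fgsea (version 1.28.0) were alternatives. The difference in response between C4-2B with VCaP and DU145 with PC3 was a contrast of the same kind of fit, with 2 residual degrees of freedom before the prior. Within a line there is 1 array per treatment and no p-value is given. There, genes with a difference past 1 (2-fold) were counted, and each list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean signal.

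The genes named in the text follow a rule fixed beforehand. It takes PRKDC and the 12 largest rises and 12 largest falls past the threshold with the same sign in 4 lines. Places left were filled by the smallest unadjusted p among genes of the same sign in 4 lines. It also takes the 4 members of each Wnt list and of each list past the threshold with the largest mean difference. Within each line it takes the 3 largest rises and the 3 largest falls besides PRKDC. For the difference between pairs of lines it takes the 5 smallest p in each direction. The fixed genes PREX1, ROCK2, VAV3 and ITGB4 are added. Any other gene named was chosen after its values were seen.

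The fits were tested on simulated data with 200 changed genes in 10 simulations over 16796 genes, with independent noise drawn from each gene's fitted variance. In the comparison of 4 pairs, 19.8% of genes changed by 0.5, 98.0% of those changed by 1 and 99.8% of those changed by 2 (log2) were called, and 0.0805% of unchanged genes. For the difference between pairs of lines, 13.2% of genes differing by 1 and 94.8% of those differing by 2 were called. The Benjamini-Hochberg threshold eases as more genes change, and each simulation held 200 changed genes. These shares therefore do not hold for data with few changed genes, where a gene changed by 1 is harder to call. For the gene list shift, each of 3 lists shifted by 0.3 was called in every simulation and none of the other 27. The simulated genes were independent of each other, so the list result says nothing about lists whose genes move together.

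Alternatives covered no filter, a filter at the 50th percentile, median centring, cyclic loess, the mean of a gene's probe sets, eBayes with a trend or robust, array weights, the fit with no block, leaving out each line, other list tests, other thresholds and the other ways to split the lines. PRKDC had 1 probe set, so no second one could be compared.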

Results

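The study asked how transcription responds when DNA-PK is depleted in prostate cancer cells, with Wnt signalling as the pathway named in its title. DNA-PK is a kinase that acts in non-homologous end joining, a repair pathway for broken DNA ends, and PRKDC encodes its catalytic subunit. Of the 4 lines, C4-2B is a bone-tropic derivative of LNCaP, VCaP came from a vertebral metastasis and carries a TMPRSS2-ERG fusion, and DU145 and PC3 came from a brain and a bone metastasis. Each line gave 1 array with non-targeting siRNA and 1 with DNAPK siRNA after 48 hours, so 8 arrays form 4 pairs. Values are log2 RMA signals, and every difference below is DNAPK siRNA minus non-targeting siRNA. Markers of the lines were read on the control arrays. KLK3, which encodes PSA, stood at 10.12 in C4-2B. In VCaP, a line known to express PSA, it stood at 4.46, close to 3.84 in DU145 and 3.68 in PC3, and did not set VCaP apart from them. ERG stood at 8.57 in VCaP and at most 3.52 in the other controls. TMPRSS2 read 9.56 in C4-2B, 9.03 in VCaP, 6.72 in PC3 and 2.18 in DU145. VIM, a mesenchymal filament gene, read 8.19 in DU145 and 7.82 in PC3 but 4.29 in C4-2B and 2.22 in VCaP.

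PRKDC was lower with DNAPK siRNA in each of the 4 lines, to very different degrees. The signal went from 9.29 to 6.76 in C4-2B, from 9.17 to 7.17 in PC3, from 9.17 to 8.08 in DU145 and from 9.80 to 9.18 in VCaP. These are log2 differences of -2.53, -1.99, -1.08 and -0.62, which leave 17.4%, 25.1%, 47.2% and 65.0% of the control signal. PRKDC had the lowest difference of all 16796 genes in C4-2B and the third lowest in PC3, but ranked 105 in DU145 and 1442 in VCaP. Its mean difference was -1.56 ± 0.86 (SD, n = 4 lines), and the limma 95% interval ran from -2.24 to -0.88. As the single gene set in advance to check the labels, it had an unadjusted p of 8.37e-04 (limma). With adjustment over all genes it did not pass (limma, adjusted p = 0.688), and 4 pairs cannot give an exact sign-flip p below 0.125.

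**Figure D1:**
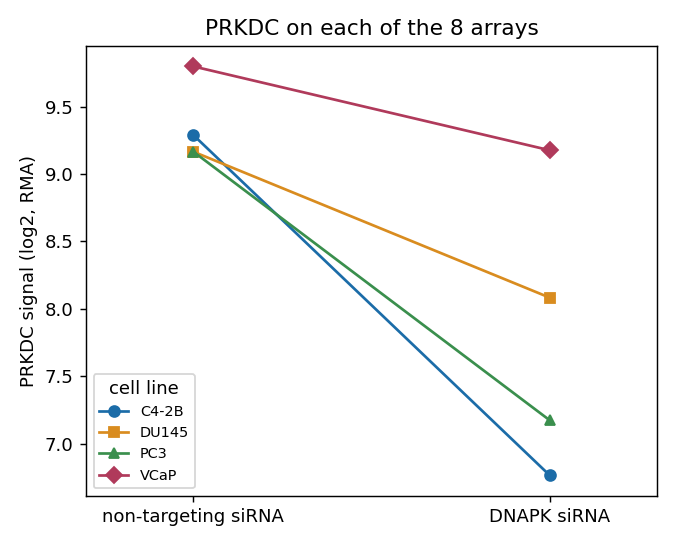
PRKDC signal (log2, RMA; vertical axis) on each array by siRNA (horizontal axis), with a line joining the 2 arrays of a cell line. The signal is lower with DNAPK siRNA in each line, from 9.29 to 6.76 in C4-2B at the most and from 9.80 to 9.18 in VCaP at the least.

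Across the 4 lines, no other gene passed the test with adjustment over all genes either. Among the genes lower in every line, TAF13 (a subunit of the general transcription factor TFIID) had a mean difference of -1.05 ± 0.49, B4GALT1 (a Golgi galactosyltransferase) -0.83 ± 0.38, AK3 (a mitochondrial adenylate kinase) -0.83 ± 0.42 and SNX5 (a sorting nexin of endosomes) -0.80 ± 0.24 (SD, n = 4 lines). STEAP4, a metalloreductase, had -0.82 ± 0.39, the Wnt and Norrin receptor gene FZD4 -0.75 ± 0.26, CARMIL1, which regulates actin capping, -0.72 ± 0.33, ENPP4 -0.71 ± 0.18, FN1 (fibronectin) -0.64 ± 0.15 and KLHL24 -0.55 ± 0.10. The microRNA genes MIR550A3 (-0.67) and MIR3689D2 (-0.59) were also among them. Among genes higher in every line, the RNA-binding protein gene MEX3A had 0.81 ± 0.38, ATOSB 0.71 ± 0.24, HSPA12B of the Hsp70 family 0.68 ± 0.28, CLDN11 of tight junctions 0.65 ± 0.16, MYPOP 0.62 ± 0.17 and C17orf58 0.60 ± 0.23. HOMER3 had 0.59 ± 0.12, the mitochondrial dicarboxylate carrier gene SLC25A10 0.58 ± 0.15 and the selenoprotein gene SELENOW 0.56 ± 0.15. GOLGA8H (0.86), the pseudogene CIDECP1 (0.74) and POMZP3 (0.56) have near-identical copies elsewhere in the genome, so their values are uncertain. None of these genes passed the test. CLDN11, HSPA12B, GOLGA8H and MYPOP had low mean control signals of 2.73, 2.71, 3.01 and 3.27, near the filter level of 2.51.

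The limma fit called 0 of 16796 genes at an adjusted p of 0.05, and the smallest adjusted p was 0.688. At an unadjusted p under 0.05 there were 1208 genes, 706 higher and 502 lower, where 839.8 would be expected by chance. That balance of directions rests on the scaling, because cyclic loess gave 531 higher and 602 lower. In 2926 genes (17.4%, against 12.5% by chance) the difference had the same sign in 4 lines, 1936 of them higher and 990 lower, and this balance rests on the scaling too, with 1696 and 1161 after median centring and 1520 and 1245 with cyclic loess. The 15154 probe sets with no name or several names above the filter also gave 0 calls, with 758 at an unadjusted p under 0.05.

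**Figure D2:**
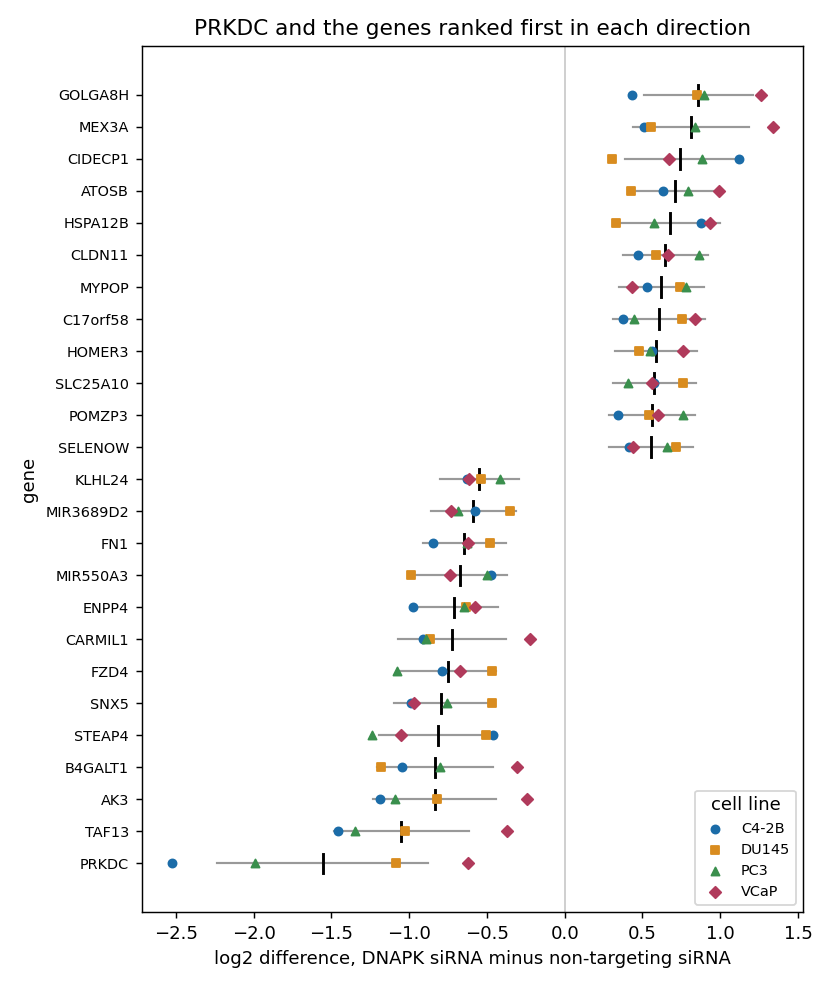
Log2 difference (DNAPK siRNA minus non-targeting siRNA; horizontal axis) of PRKDC and of the 12 genes ranked first by limma in each direction (vertical axis). Coloured points are the 4 cell lines, black ticks the means and grey bars the limma 95% intervals; TAF13 has the lowest mean after PRKDC, at -1.05, and GOLGA8H the highest, at 0.86.

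The 5 Wnt lists showed no shift that passed by camera, fry or fgsea. Wnt target genes had a median mean difference of -0.04 over 43 measured members, 16 above 0 and 27 below (camera, adjusted p = 0.145). In each line this list had a median below 0, at -0.03 in C4-2B, -0.07 in DU145, -0.00465 in PC3 and -0.04 in VCaP. Its members with the largest differences were SNAI2, an EMT transcription factor (-0.45), CEMIP (-0.41), JUN (0.39) and ID2 (0.35), and AXIN2, a feedback gene of the pathway named under the beta-catenin components too, had -0.27 with a value below 0 in each line. Wnt antagonists had a median of -0.08 over 19 members (adjusted p = 0.145), with SOST at -0.42, SFRP4 at -0.32, KREMEN2 at -0.25 and SFRP1 at 0.24. Beta-catenin components had a median of 0.02 over 48 members (adjusted p = 0.962), led by the co-activators BCL9L (0.58) and PYGO2 (0.30) and by APC (0.29). Ligands and receptors had a median of 0.01 over 35 members (adjusted p = 0.448), with FZD4 at -0.75, WNT10A at 0.45, WNT2B at 0.34 and FZD6 at 0.34. Non-canonical components had a median of 0.02 over 36 members (adjusted p = 0.636), with CAMK2G at 0.49, RAC2 at 0.48, PRKCB at -0.36 and PLCB3 at 0.32. Many of these gene means rested on VCaP. Without that line FZD6 had 0.06, APC 0.19, ID2 0.0150, PLCB3 0.08, BCL9L 0.28, CAMK2G 0.25, RAC2 0.26, SFRP1 0.11, KREMEN2 -0.16 and SNAI2 -0.24, while without DU145 CEMIP had -0.19, AXIN2 -0.16, KREMEN2 -0.14, SFRP1 0.41, WNT10A 0.69 and ID2 0.54. SNAI2 had -0.75 without PC3. SFRP4, PRKCB, WNT2B and WNT10A had low mean control signals of 2.74, 3.08, 3.29 and 3.41, near the filter level of 2.51. In the lists of beta-catenin components, of ligands and receptors and of non-canonical components, the median lay above 0 while camera, which sets a list against all other genes, leaned down. The signs of these medians rest on the scaling, since with cyclic loess they were -0.00971, -0.000456 and -0.00747. With p-values adjusted over the list alone, FZD4 was the only Wnt list member to pass (limma, adjusted p = 0.0203), and over all genes 0 members passed.

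PREX1, ROCK2, VAV3 and ITGB4, genes of cell migration, had been fixed in advance. PREX1, a Rac exchange factor, had a mean difference of 0.67 ± 0.89, from -0.29 in C4-2B to 1.83 in VCaP (limma, adjusted p = 0.688), and 0.28 without VCaP. ROCK2 had -0.14 ± 0.35 and integrin gene ITGB4 -0.11 ± 0.29, with adjusted p of 0.826 and 0.853. Without DU145, PC3 or VCaP, ITGB4 had -0.0352, -0.0410 and -0.24, and ROCK2 had -0.23, -0.22 and 0.0216. ITGB4 read 2.69 in the C4-2B control and 2.85 in the VCaP control, near the filter level of 2.51. It read 6.93 in the DU145 control and 9.21 in the PC3 control. Its differences were -0.33 in DU145, -0.32 in PC3, -0.08 in C4-2B and 0.29 in VCaP. VAV3 lay below the expression filter, at 1.86 in the C4-2B control and 3.56 in the VCaP control, and was not tested.

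Of the 30 lists, 3 passed with camera's preset correlation, 0 with an estimated one, 0 by fry and 9 by fgsea. Unfolded protein and ATF4 response genes leaned down in the mean over lines, with a median of -0.24 over 37 members, 12 above 0 and 25 below (camera, adjusted p = 6.84e-04, or adjusted p = 0.632 with an estimated correlation). The lower values were mostly those of VCaP (median -0.55) and C4-2B (-0.29), while PC3 had -0.07 and DU145 0.04, with 21 of 37 members above 0. The list did not move as 1 group in VCaP, where 14 of 37 members lay above 0, 6 of them past 1. SLC7A11, the cystine transporter, had -1.15 ± 0.80, CHAC1, which degrades glutathione, -0.83 ± 0.91, the stress gene NUPR1 -0.76 ± 0.72 and SESN2 -0.70 ± 1.27. Without VCaP, SESN2 had -0.12 and CHAC1 -0.49, and without DU145, NUPR1 had -0.48. None of these members passed alone. Some ER chaperone genes of the same list lay above 0, with DNAJB11 at 0.49 and PDIA4 at 0.43 (named after their values were seen). Both of these means rested mostly on VCaP. With the preset correlation, leaving out C4-2B ended the call (median -0.18, adjusted p = 0.0629), and leaving out VCaP gave a median of -0.12. DNA replication genes and E2F targets rose as a group in the mean over lines, with a median of 0.13 over 51 members, 42 above 0 (adjusted p = 0.00893, or adjusted p = 0.716 with an estimated correlation). PC3 went the other way, with a median of -0.19 and 40 of 51 members below 0, against 0.46 in DU145, 0.14 in C4-2B and 0.11 in VCaP. Its leading members were CCNE2 (0.41), TIPIN (0.39), GINS4 (0.38) and E2F1 (0.36), of which CCNE2 had 0.18 without VCaP and GINS4 0.25 without DU145. This call rested on DU145, since without that line the median was 0.02 and the direction of the test turned (adjusted p = 0.903), and without PC3 the median was 0.24. MYC targets and ribosome biogenesis genes had a median of 0.11 over 27 members, 23 above 0 (adjusted p = 0.0290, or adjusted p = 0.632 with an estimated correlation), led by ODC1 (0.38), RRP9 (0.35), SRM (0.31, or 0.20 without VCaP) and NIP7 (0.31). Leaving out C4-2B, DU145 or VCaP ended that call, with medians of 0.09, 0.07 and 0.15 and adjusted p of 0.0682, 0.295 and 0.0537, and so did the fit with no block (0.0508).

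By camera, fry and camera with an estimated correlation none of the other lists passed. Of those given here, fgsea called interferon response genes (adjusted p = 0.0130), TGF-beta and BMP genes (0.0262), hypoxia and glycolysis genes (0.0274), mitosis genes (0.0310) and mesenchymal and matrix genes (0.0310). With camera, TGF-beta and BMP genes had a median of -0.08 and medians below 0 in each line (adjusted p = 0.0541), mitosis genes -0.05 (0.0719) and interferon response genes 0.15 (0.0719). The interferon value rested on PC3 (median 0.77), against -0.03 in C4-2B, -0.11 in DU145 and -0.09 in VCaP. That of the hypoxia list rested on VCaP (0.91), against -0.02 in C4-2B, 0.15 in DU145 and -0.19 in PC3. Hypoxia and glycolysis genes (0.21), oxidative phosphorylation genes (0.09), cholesterol synthesis genes (0.10) and mesenchymal and matrix genes (-0.02) all had an adjusted p of 0.145. For non-homologous end joining, the pathway of DNA-PK itself, the median was 0.06 (adjusted p = 0.161), for homologous recombination and Fanconi genes 0.04 (0.448) and for PI3K-like kinases and their partners 0.11 (0.448). Medians for Hedgehog (-0.03, adjusted p = 0.184), immediate-early and heat-shock (0.03, 0.256), Notch (-0.04, 0.291), epithelial (-0.00415, 0.530), NF-kB and inflammatory (0.01, 0.893) and p53 target genes (-0.00384, 0.995) were near 0 in the mean over lines. Of these, NF-kB and inflammatory genes had 0.24 in PC3, against 0.04 in C4-2B, -0.02 in DU145 and 0.02 in VCaP. Immediate-early and heat-shock genes had 0.28 in DU145, against 0.03 in C4-2B, 0.09 in PC3 and 0.02 in VCaP. In the mean over lines, markers of other cell types also stayed near 0, with immune markers at -0.03 (0.448), fibroblast and endothelial markers at 0.03 (0.597), neuroendocrine genes at -0.04 (0.433) and line identity markers at -0.00415 (0.433). Line identity markers differed in sign between lines, with medians of -0.25 in PC3, -0.14 in C4-2B, 0.06 in DU145 and 0.19 in VCaP. For immune, fibroblast and p53 lists, the signs of the median, mean and test differed. Adjusted over the list alone, 1 mesenchymal gene passed (FN1, limma adjusted p = 0.0185).

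**Figure D3:**
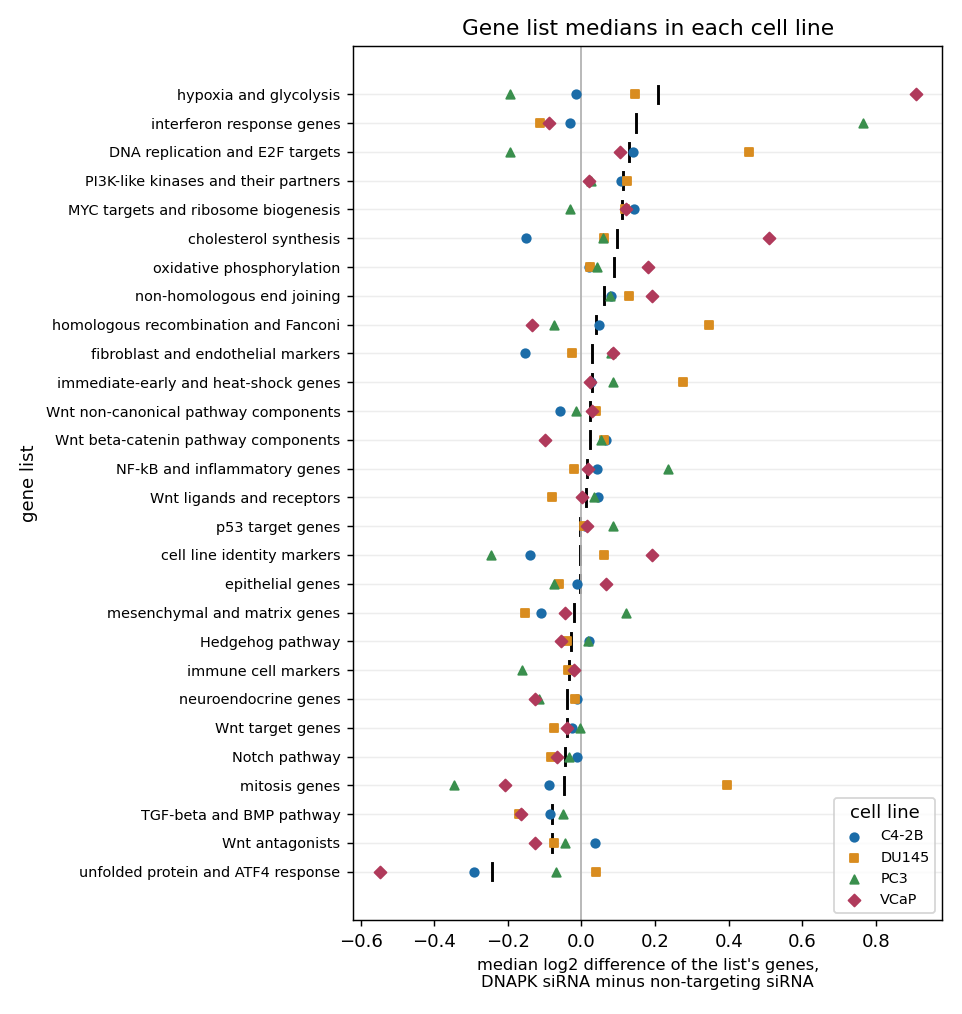
Median log2 difference of the gene lists reported (vertical axis) in each cell line (coloured points; horizontal axis), with a black tick at the median of the mean over lines. The medians that lie farthest from 0 are those of hypoxia and glycolysis genes in VCaP (0.91) and of interferon response genes in PC3 (0.77).

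Within single lines, where 1 array per treatment allows no test, larger coordinated differences were seen. In VCaP, hypoxia and glycolysis genes had a median of 0.91, above all 10000 matched random lists, with 14 of 30 past 1, among them P4HA1 (2.19), PFKFB3 (1.88), HK2 (1.87) and LDHA (1.64). Cholesterol synthesis genes had 0.51 there and the unfolded protein and ATF4 list -0.55, with 16 members past -1 and 6 past 1. In PC3, interferon response genes had a median of 0.77, with 15 of 41 past 1, among them IFI6 (1.96), MX1 (1.87), IFI44 (1.80) and IFITM1 (1.74). Cell cycle genes went opposite ways. In DU145 mitosis genes had 0.40 and DNA replication genes 0.46, with 46 of 48 and 50 of 51 above 0, and homologous recombination and Fanconi genes 0.35. Mitosis genes had -0.35 in PC3, with 0 of 48 above 0, and -0.21 in VCaP, and DNA replication genes had -0.19 in PC3. Hypoxia and glycolysis genes had -0.19 in PC3, and TGF-beta and BMP genes -0.17 in DU145. In C4-2B the unfolded protein and ATF4 list had -0.29, with 1 of 37 above 0. Each of these medians lay outside all 10000 random lists, and their members were named after their values were seen. The random lists take genes as independent. For the lists here, the inter-gene correlation estimated by camera ran from -0.0047 (TGF-beta and BMP genes) to 0.73 (mitosis genes). With 1 array per treatment, a difference between cultures cannot be told apart from an effect of the siRNA. Immune cell markers had a median of -0.16 in PC3.

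Genes past 1 on the log2 scale numbered 41 higher and 57 lower in C4-2B, 51 and 137 in DU145, 89 and 91 in PC3, and 216 and 406 in VCaP. PRKDC is counted there where it fell past 1, but it is left out of the genes named next. The highest differences in VCaP were those of PLOD2, a collagen lysyl hydroxylase (2.66), MIR210HG, the host gene of a hypoxia-induced microRNA (2.54), and PDIA3 (2.45, from 3.35 to 5.80). The lowest were those of LRRC31 (-2.93), MYBPC1 (-2.88) and BEST1 (-2.81). PC3 had MS4A7 (2.33), IFI6 (1.96) and MYPN (1.93) against RNU7-27P (-2.72), the collagenase gene MMP1 (-2.05) and RNU6-14P (-1.86). DU145 had DDTL (1.55), RNY4P23 (1.53) and ZNF90 (1.46) against POM121L9P (-2.28), MIR1587 (-2.23) and complement gene C3 (-2.20). C4-2B had ATOH1 (1.53), GOLGA8J (1.51) and IGLV3-27 (1.35) against MIR596 (-2.07), LOC100287834 (-1.81) and RNU7-70P (-1.61). Several of these genes had signals below the level of the filter in 1 array of the pair, such as ATOH1, which went from 2.40 to 3.94, and the small RNA gene RNU7-27P, which went from 4.28 to 1.56.

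The differences of the lines correlated weakly. Noise in single arrays pulls such correlations towards 0, so they do not measure how much of the response was shared. In C4-2B the SD of the differences was 0.288 above the expression filter and 0.281 below it, and in VCaP 0.462 and 0.396. Across genes, which are not independent replicates, the Pearson correlation of the differences between 2 lines ran from 0.01 (DU145 with VCaP) to 0.14 (C4-2B with PC3), with a mean of 0.06 over 6 pairs. Genes past 1 in the same direction numbered 7 in C4-2B with PC3, where 0.526 would be expected from independent lists, against 2 in opposite directions. C4-2B shared 6 with DU145 and 11 with VCaP, against 2 and 3 in opposite directions. PC3 and VCaP shared 13 (3.34 expected) against 7 opposite, DU145 and PC3 8 (1.01 expected) against 7, and DU145 and VCaP 7 (3.97 expected) against 10. The shared counts for the pairs among C4-2B, DU145 and PC3 include PRKDC, the target of the siRNA, which fell past 1 in each of these lines. Past 1 in at least 3 lines there were 5 genes lower (PRKDC, TAF13, MIR4660, RNU6-14P and RNU7-65P, named after their values were seen) and 0 higher.

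The response was also compared between C4-2B with VCaP and DU145 with PC3, a pairing of the lines fixed in advance. Unfolded protein and ATF4 genes had a median of -0.40 in C4-2B with VCaP and -0.03 in DU145 with PC3, a median difference of -0.31 (camera, adjusted p = 0.00417, or adjusted p = 0.967 with an estimated correlation). Hypoxia and glycolysis genes differed by 0.52 (adjusted p = 5.15e-05) and interferon response genes by -0.34 (adjusted p = 0.00417), each with adjusted p = 0.967 with an estimated correlation. Leaving out a line leaves 1 line on that side, which is then assumed to vary like the other pair. Without VCaP the hypoxia difference was -0.01 (adjusted p = 0.982), and without PC3 it was 0.36 (0.0502) and the interferon difference 0.04 (0.123). Leaving out C4-2B ended the unfolded protein call (-0.46, adjusted p = 0.429) and the interferon call (-0.35, 0.429), which the stricter expression filter ended too (-0.32, 0.153). By fry, 0 lists differed. No single gene passed (limma, 0 of 16796, smallest adjusted p = 0.991), with 621 at an unadjusted p under 0.05. Ranked first were ULBP1, a ligand of the NKG2D receptor (-2.05), EEF1DP3 (-1.62), YY2 (-1.84), RN5S294 (-1.48) and CHAC1 (-1.52) in the lower direction. In the higher direction they were RNU7-26P (1.66), HOXA2 (1.29), RN5S417 (1.3), the carboxylate transporter gene SLC16A9 (1.25) and the adhesion gene CEACAM6 (1.47).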

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

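The tests of the size of the knockdown in VCaP, of noise and of culture conditions for its hypoxia genes, of immune cells in PC3, of dose for the shared falls and rises, and of the order of the falls were chosen after the results were seen. Of 92 sets of 4 values (1 for each line) looked at, 9 held a value far from the other 3. Chance would give about 4.6 (1 in 20) if the lines had equal spread and the sets were not chosen by their values. Neither holds, so 4.6 is not the chance count here. The SD of the differences was 0.462 in VCaP against 0.288 to 0.334 in the other lines, and many genes were named for a large mean difference.

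In PC3 the interferon response list lay far from the other lines, with a median of 0.77, and it differed between the pairs of lines by -0.34 with a preset correlation (adjusted p = 0.967 with an estimated correlation). Immune cells in the culture stay open, since the immune markers, with a median of -0.16 in PC3 (also far from the other lines), went both ways, 4 above 0 and 7 below. MS4A7 (2.33) and FCGR3A (0.86) were the highest of them and CD79A (-0.54) the lowest. PTPRC, LYZ, CD14, CD3D and CD3E lay below the expression filter, with PC3 differences from -0.30 (LYZ) to 0.13 (PTPRC). Interferon genes transcribed by the PC3 cells may have a part, which stays open because the largest difference among IFNB1, IFNL1, IFNL2 and IFNL3 was 0.53, and IFNB1 and IFNL1 lay below the expression filter. Sensing of the siRNA and loss of DNA-PK were not tested, and 1 array for each treatment confounds both with a difference between cultures.

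VCaP had 622 genes past 1 although PRKDC was lowered least there, by a difference 1.25 above the mean of the other lines, which argues against a larger loss of the transcript, as far as 1 probe set shows and with protein not analysed here. Array noise is a candidate source of part of that count, since below the expression filter the SD of the VCaP differences was 1.35 times the mean of the other lines. The hypoxia genes differed between the pairs of lines by 0.52 with a preset correlation (camera, adjusted p = 0.967 with an estimated correlation). For them, noise that falls on each gene independently is argued against. A further 23 measured hypoxia genes had a median of 0.50 in VCaP, at the 100th percentile of matched random lists, so the shift was not that of glycolytic genes alone. They include PLOD2 (2.66) and MIR210HG (2.54), the highest differences of all genes in VCaP, so the list may not be independent of values already seen. The random lists take genes as independent. In PC3, DU145 and C4-2B the same genes had medians of -0.14, -0.10 and -0.05, at percentiles 0.12, 1.28 and 3.93. Oxygen or density of the VCaP cultures cannot be told apart from a response of VCaP cells, since there was 1 array for each treatment and the highest median in another line was 0.15.

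Under a dose effect genes would follow PRKDC across lines. By covariance with it the real assignment of lines ranked 19 of 24 over 118 shared falls and 24 of 24 over 55 shared rises, and 14 and 16 with each line divided by its SD. These ranks decide nothing, since genes chosen by their mean difference favour VCaP, where the shared falls averaged 0.981 below 0 against 0.527 to 0.577 in the other lines. The order C4-2B, PC3, DU145, VCaP, tested later still, held for 4 of the 12 named falls (TAF13, AK3, CARMIL1 and ENPP4, where 0.5 would be expected by chance). Over 989 genes lower in every line this order ranked 2 of 24 after division by the SD but 13 without it, so dose, which may order some of the falls, cannot be told apart from chance with 4 lines, and a match of the siRNA to other transcripts, which bears on any shared difference, was not examined because its sequence was not used here.

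Medians far from those of the other lines were also found for Wnt beta-catenin components in VCaP (-0.10), p53 targets in PC3 (0.0861), MYC targets in PC3 (-0.0319) and oxidative phosphorylation in VCaP (0.18). Among named genes, the VCaP values of BCL9L (1.48), PLCB3 (1.03) and CARMIL1 (-0.22) lay far from the rest. The unfolded protein and ATF4 list differed between the pairs of lines by -0.31 with a preset correlation (adjusted p = 0.967 with an estimated correlation).

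Of the 35 ways to split the 8 arrays into groups of 4, 8 part every pair of a line as the real one does, 24 part 2 pairs and 3 part none. The 8 splits that part every pair are too few for a share under 0.05. By limma the real split gave 0 genes at an adjusted p of 0.05, a count that all 8 reached, with 0 in the highest other. At an unadjusted p under 0.05 it gave 1208 genes, reached by 1 of 8 (itself), with 924 in the highest other. It gave 3 gene lists by camera, reached by 6 of 8, with 7 in the highest other.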

How the results depend on the processing

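The list medians within a line that lay outside all random lists were recomputed with no filter, the stricter filter, median centring, cyclic loess and the mean of probe sets as a test chosen after seeing the data, and all 65 values kept their sign and moved by less than the spread between lines. PRKDC was lower in each fit run, by a mean difference from -1.23 (without C4-2B) to -1.87 (without VCaP). By limma, 0 genes passed an adjusted p of 0.05 under each alternative, with 1208 at an unadjusted p under 0.05 in the planned fit, 63 with no block and 828 to 1550 otherwise. Of the values of the 59 named genes under the alternatives, 756 kept their direction and their side of the threshold and 1 turned, that of ROCK2, which ran from -0.23 to 0.0216 when a line was left out. The number of lists that passed was 3, and it was 5 with no filter, the stricter filter, eBayes trend or array weights, 6 with cyclic loess, 9 with fgsea, and 0 with fry or an estimated correlation. It was 3 to 6 when a line was left out. With fry and with an estimated correlation the calls for unfolded protein and ATF4 genes (-0.24), DNA replication genes (0.13) and MYC targets (0.11) were lost at the same medians, and with no block that for MYC targets (0.11). Leaving out a line gave medians of -0.28 to -0.12, 0.0157 to 0.24 and 0.0688 to 0.15 for these lists. The test of beta-catenin components turned with the stricter filter (0.0302), array weights (0.0315), and eBayes trend, fry and fgsea (0.0220 in each), and that of non-canonical components with fry (0.0230). When a line was left out, beta-catenin components ran from -0.00687 to 0.0185, non-canonical components from -0.0468 to 0.0278, ligands and receptors from 0.000432 to 0.0277, antagonists from -0.0831 to -0.0379 and target genes from -0.0502 to -0.0242. The test turned for beta-catenin components without DU145 or VCaP, for non-canonical components without C4-2B and for ligands and receptors without DU145. Non-canonical components had -0.0397 with array weights. Antagonists had -0.0172 with no filter and -0.0451 with array weights, and target genes -0.0171 with array weights, with no call in any of these. The number of lists that differed between the pairs of lines was 3, against 0 with fry or an estimated correlation, 7 with C4-2B and DU145 set against the rest, 5 with C4-2B and PC3 set against the rest, and 2 to 5 when a line was left out, where the line that remains on its side is assumed to vary like the other pair. The interferon difference then ran from -0.82 to 0.0378 and the hypoxia difference from -0.00979 to 1.11. At a difference of 0.58 within a line there were 888 genes in C4-2B, 1312 in DU145, 1281 in PC3 and 2918 in VCaP, more by construction. The mean correlation between lines ran from 0.0507 to 0.102. The cause of the other changes was not tested, and signal over background was not measured.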

Other observations

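The unfolded protein and ATF4 list was divided in VCaP. The amino acid and redox genes SESN2 (-2.44), SLC7A11 (-2.30), CHAC1 (-1.87) and MTHFD2 (-1.64) lay far below 0, while the ER folding genes PDIA4 (1.65), DNAJB11 (1.62), HSPA5 (1.54) and SDF2L1 (1.37) lay far above it. In C4-2B 36 of the 37 members were below 0, from CHAC1 (-1.31), CTH (-1.29) and SLC7A11 (-1.04) to the ER genes SEL1L (-0.59), DNAJB9 (-0.54), HERPUD1 (-0.52), PDIA4 (-0.25) and HSPA5 (-0.11). These genes were picked after their values were seen, and 1 array for each treatment gives no test.

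The BMP response genes ID1 (2.40), ID3 (1.66) and ID2 (1.37) were among the highest of the TGF-beta and BMP list in VCaP, where the receptor gene BMPR1B was at -1.06. In DU145, ID3 was at -1.09 and SMAD6 at -0.79. BUB3, a spindle checkpoint gene, was below 0 in each line, with a mean difference of -0.48, while the mitosis list as a whole had medians of opposite sign in DU145 and PC3. Cholesterol synthesis genes in VCaP included INSIG1 (1.09), STARD4 (1.07) and HMGCS1 (0.96), and in C4-2B the same list had a median of -0.15.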
